A study of Mus musculus with 12 samples.

How the data were processed

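Poly-A RNA of 12 samples of MC38 cells was sequenced as 150 bp paired reads, in 4 groups of 3 libraries: wild-type and Smarcd1 knockout cells, each without and with IFN. The authors' processing notes name CASAVA, Trimmomatic 0.36, FastQC 0.11.2 and HISAT2 2.1.0 with genome build GRCm38. The program that counted reads, the one that computed TPM, the strand setting and the annotation release are not given in the sources used here. The deposited tables hold raw counts per Ensembl gene and TPM computed by the authors, for the same 12 libraries and 51826 genes, and 0 columns of other samples. Counts were whole numbers, and the TPM of a library summed to between 999728.7 and 999898.1. Genes at counts of 4, 6 or 8 outnumbered their odd neighbours 1.386 to 1.649 times, as when both mates of a pair are counted, so the counting intervals given here may be too narrow.

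Groups were taken from the sample titles. In 6 samples the genotype and treatment characteristics disagree with the titles, exchanging wild-type cells with IFN and untreated knockout cells; the short sample codes go with the titles. The level of Smarcd1 was checked under both groupings, and counts of called genes are given for both. Nothing in the labels says that the 3 samples of a group were separate cultures, or how many knockout clones were used. The p values therefore measure only the spread between these samples, and the intervals on ratios of counts cover counting error only. Pairs of libraries in a group had a chi-square per gene of 12.53 to 143.9 over counting noise and a Pearson correlation of log2 CPM of 0.9798 to 0.9891, so no library was a copy of another. Libraries held 31752685 to 45721356 counts, so 3 counts over a group lie far below the minimum of 2 CPM set for most named genes.

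Gene identifiers were matched to GENCODE M21 (51633 genes, 99.63%) for positions, GC content and overlaps between exons. Overlaps with another annotated gene covered 10.7% to 29.2% of the exonic bases of Aldh1l2, Bnip3, C1qtnf1, Cd274, Cdk4, Ctgf, Gadd45a, Hacd4, Hmgcs1, Mmp19, Ppp1r14c, Rfc5, Spp1 and Tmem184a; larger ones are given with the gene. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 16676, and libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries (8 residual degrees of freedom, robust estimation, common biological coefficient of variation 0.168, median prior degrees of freedom 4.32). There were 5 contrasts: IFN in wild-type cells, IFN in knockout cells, knockout without IFN, knockout with IFN, and the interaction. The Benjamini-Hochberg method was applied to each contrast separately, with a threshold of 0.05, and a gene is said to have risen or fallen where it passed. Values after ± are standard deviations for CPM and standard errors for log2 fold changes. These standard errors were computed as the absolute log2 fold change over the square root of the F statistic of its test. They are approximate, above all where a group lies near 0 counts. Adjusted p values are from edgeR for genes and from limma's camera for lists, unless another tool is named. A fold against a group at 0 counts was computed against a floor of 3 counts over the group; with 1 to 3 counts in the lower group a ratio with a 95% counting interval is given.

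The grouping, the contrasts, the threshold, the rule for naming genes and most alternatives were set before the data were examined. Genes named in a comparison passed the threshold, had a mean of at least 2 CPM over all libraries, showed no overlap between the libraries of the groups compared (not required for the interaction), and had no clone-based or predicted symbol. Of these, the 8 with the largest change in each direction were named. Members of a fixed panel of 31 genes and up to 4 members with the smallest p of each list were named too, without those conditions. Some genes that this rule names are not reported here. No overlap between 3 and 3 libraries arises by chance in 10% of genes.

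Lists in 36 groups, with 913 entries over all lists, were written from general knowledge. They covered interferon responses, antigen presentation, cell cycle, metabolism, stress, matrix, signalling, chromatin and markers of other cell types. Some genes are in more than 1 list, such as Cxcl9 in the interferon gamma response and the chemokine lists, so calls of such lists are not independent. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1, on voom weights) with the preset correlation of 0.01 between genes, and again with the correlation estimated for each list. Markers of T and NK cells (3 tested members) and of melanocytes (2) were too few to test. Counts of list members past the threshold are given over all genes, and also adjusted over the list alone.

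Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a stricter filter (10 counts in each library of a group and a mean CPM of 1), only the libraries compared, an additive term for the replicate number, no robust estimation, an added requirement of a 2-fold change, limma on log2 of the deposited TPM plus 1 or plus 0.1, limma with a mean TPM of at least 1, fry or an estimated correlation for lists, groups from the characteristics, and leaving out each library in turn. Leaving out both libraries farthest from their groups, removing each library's trend with GC content, and leaving out chromosomes 9 and 16 were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

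The edgeR model was tested on simulated data with the same design and depths and with the spread estimated for each gene. For the knockout effect it recovered 25.4%, 73.1% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold (67, 67 and 66 genes), with 6 unchanged genes called among 16493 in the fit. For the interaction it recovered 8.96%, 50.7% and 90.9%. DESeq2 recovered 43.3%, 83.6% and 98.5% for the knockout effect, with 33 unchanged genes called. Camera called the 1 raised list (33 genes) and 0 of the 33 unchanged lists. Genes were simulated independently of each other, so this does not test camera on lists whose members vary together. Starting levels were those of wild-type cells, only the genes counted above were changed, and no library was made to stand apart. The shares recovered therefore need not hold for the data, where many more genes were called and some libraries stood apart.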

Results

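RNA sequencing was used to compare MC38 cells, a mouse colorectal carcinoma line, with and without guide RNA-directed knockout of Smarcd1 and with and without added interferon (IFN). Smarcd1 encodes a subunit of the SWI/SNF (BAF) chromatin remodelling complexes, and the title of the series names PD-L1 expression and proliferation as its subjects. Which interferon was added, its dose and its duration were not given in the sources used here. The 12 libraries formed 4 groups of 3: untreated wild-type cells, wild-type cells with IFN, untreated knockout cells and knockout cells with IFN. Wild-type libraries held 32507348 to 36394538 counts without IFN and 31752685 to 34884059 counts with IFN. Knockout libraries held 39899026 to 45721356 counts without IFN and 37270418 to 44174663 counts with IFN. Between 22070 and 23314 genes had a count in a library, and 16676 genes passed the filter for testing. On principal components of log2 CPM, the first component (37% of the variance) separated knockout from wild-type libraries and the second (20.1%) separated libraries with and without IFN. The third (8.63%) set replicate 2 of the untreated wild-type cells apart from the other 11 libraries, with a score of -50.92. In that library 4.82% of counts came from mitochondrial genes, against 1.61% and 1.62% in the other untreated wild-type libraries.

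The targeted gene was examined first, because the titles and the characteristics in the labels disagreed for 6 libraries. Smarcd1 (ENSMUSG00000023018, chromosome 15, 99702129 to 99713991, GRCm38) had 90.9 ± 13.1 CPM (mean ± SD, n = 3) in untreated wild-type cells and 51.5 ± 3.04 CPM in untreated knockout cells, grouped by the titles. With IFN the values were 103 ± 18.7 and 59.8 ± 0.968 CPM. Each of the 6 knockout libraries (49.4 to 60.6 CPM) lay below each of the 6 wild-type libraries (81.8 to 123 CPM). The log2 fold change was -0.82 ± 0.13 (SE) without IFN (adjusted p = 0.000814) and -0.79 ± 0.13 with IFN (adjusted p = 0.00109). IFN itself gave 0.18 ± 0.13 in wild-type and 0.22 ± 0.13 in knockout cells, which did not pass the test (adjusted p = 0.433 and 0.314). With groups taken from the characteristics instead, the knockout difference without IFN was 0.18 ± 0.13 (adjusted p = 0.433). Editing by a guide RNA changes the coding sequence and need not remove the transcript, so the remaining Smarcd1 counts do not measure the protein. Of its exonic bases, 12.7% overlapped genes on the opposite strand. Among the related subunits, Smarcd2 did not pass the test in any of the 4 comparisons of groups. Smarcd3 was 0.37 ± 0.11 higher in untreated knockout cells (adjusted p = 0.0442), a call that was lost (adjusted p 0.0889 to 0.103) when replicate 2 or 3 of the untreated wild-type cells or any untreated knockout library was left out. Of the exonic bases of Smarcd3, 50.1% overlapped genes on the opposite strand.

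**Figure D1:**
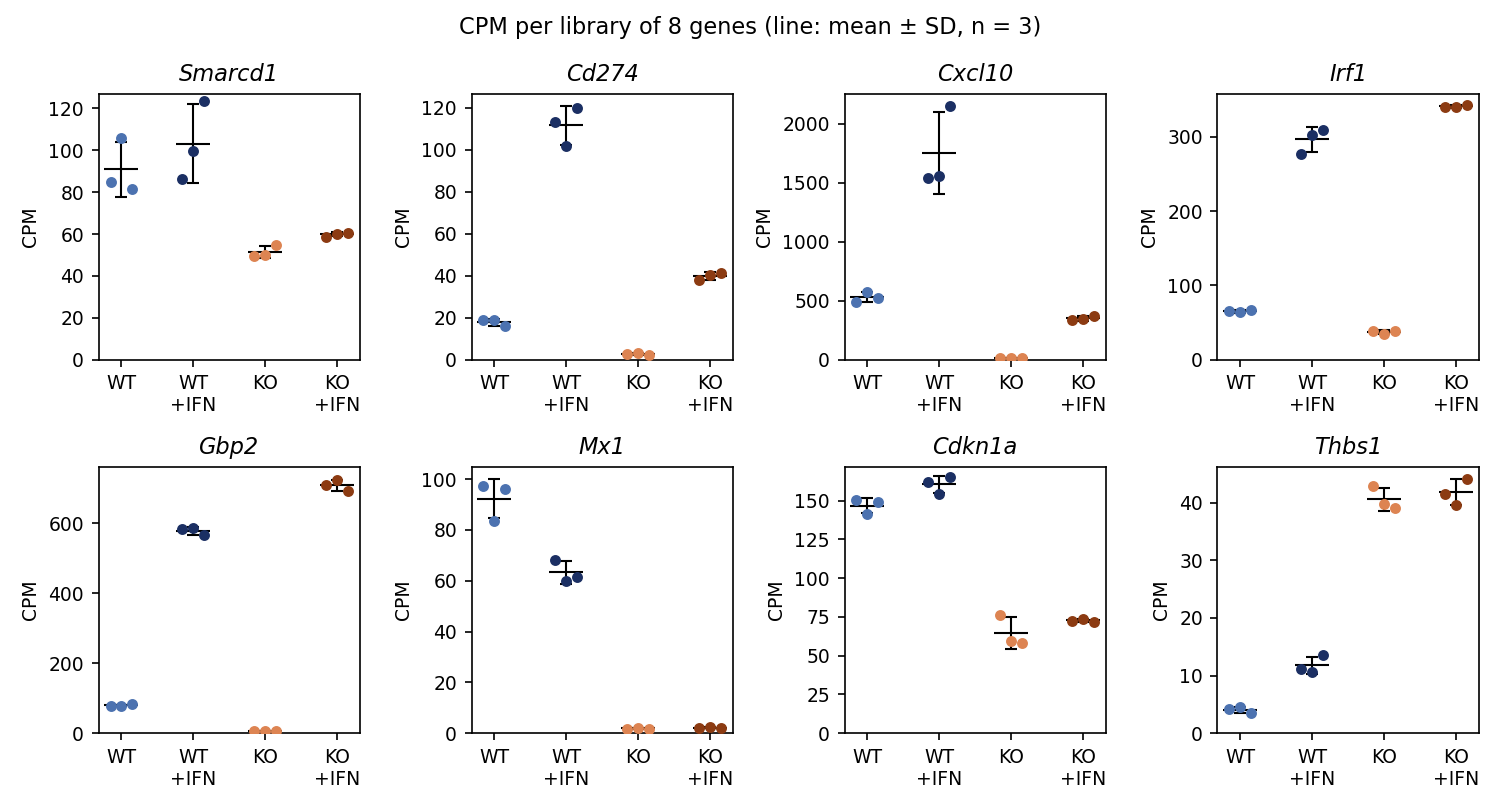
TMM-normalized CPM (linear axes from 0) of 8 genes in each of the 12 libraries, with a point per library and a line and bars for the mean ± SD (n = 3 per group). Smarcd1 was lower in all knockout libraries, Cd274 rose with IFN in both genotypes (to 112 CPM in wild-type and 39.9 CPM in knockout cells), and Mx1 stayed near 2 CPM in knockout cells.

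The first comparison asked how wild-type cells responded to IFN. Cd274 (chromosome 19, 29367455 to 29388095), which encodes PD-L1, rose from 17.9 ± 1.64 to 112 ± 9.26 CPM (mean ± SD, n = 3), a log2 fold change of 2.65 ± 0.11 (SE, adjusted p = 2.72e-08). Serpina3f (chromosome 12, 104214544 to 104221129) had 0 counts in the 3 untreated libraries and 3100 with IFN, at least 1100-fold higher. The other largest increases were in the chemokine gene Cxcl9 (4.88 ± 0.24, adjusted p = 7.01e-07), Serpina3g (4.17), the transcription factor gene Irf8 (3.71), Gja4 (3.69), Apol6 (3.39), Ubd (3.38) and the guanylate-binding protein gene Gbp4 (2.88 ± 0.10, adjusted p = 9.53e-09). The largest decreases were in Gpr35 (-2.84), C1qtnf1 (-2.01), the mitophagy receptor gene Bnip3 (-1.75 ± 0.10, adjusted p = 3.34e-07), Htra3 (-1.67), Mmp19 (-1.65), Akap12, Fam129a and Hacd4 (each near -1.60). The call for Gpr35 (adjusted p = 0.0423) was lost without any of 5 libraries, replicates 1, 2 and 3 of the untreated and 1 and 2 of the treated wild-type cells (adjusted p 0.0641 to 0.116).

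In total, IFN changed 1564 genes in wild-type cells, 777 higher and 787 lower, of which 194 and 158 changed at least 2-fold. The interferon gamma response list rose: 34 of its 39 tested members were higher over all genes and 37 when adjusted over the list alone, with a median log2 fold change of 1.63 (camera adjusted p = 4.72e-57, and 9.36e-05 with an estimated correlation). Its members included Irf1 (2.18 ± 0.08, adjusted p = 9.53e-09) and Gbp2 (2.87 ± 0.11, adjusted p = 1.18e-08). By contrast, the type I interferon-stimulated list was not called (median -0.17, adjusted p = 0.578): 4 of its 38 members were higher, such as Parp14 (0.90) and Zbp1 (0.81), and 6 were lower, or 4 and 7 adjusted over the list alone. Chemokines and cytokines rose (12 of 20 members over all genes and adjusted over the list alone, median 0.844, adjusted p = 0.0234 with an estimated correlation), with Cxcl1 at 2.52 and Cxcl10 at 1.72. TNF and NF-kB targets rose as well (16 of 21, or 17 adjusted over the list alone, median 0.598, adjusted p = 0.00658 with an estimated correlation), among them the inhibitor gene Nfkbie (1.03).

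Genes of cholesterol biosynthesis rose together in IFN-treated wild-type cells: 17 of 24 tested members were higher (20 adjusted over the list alone), with a median of 0.721 and an adjusted p of 0.000973 with an estimated correlation. They included Hmgcs1 (1.03), which encodes a synthase early in the pathway, and the feedback regulator gene Insig1 (0.99). MYC targets and ribosome biogenesis genes rose by less (14 of 34, 18 adjusted over the list alone, median 0.279, adjusted p = 0.0168 with an estimated correlation). Glycolysis and hypoxia genes fell (16 of 31, 20 adjusted over the list alone, median -0.475, adjusted p = 0.0197 with an estimated correlation), led by Bnip3, P4ha2 (-0.95) and Pfkp (-0.70). Genes of MHC class I presentation (8 of 23 higher, 13 adjusted over the list alone, median 0.345) included Nlrc5 (1.25) and Tap1 (1.20), but the list's call was lost with an estimated correlation (adjusted p = 0.0923). The same held for interferon signalling parts (6 of 22 higher, adjusted p = 0.0611 with an estimated correlation) and immediate early genes (14 of 27 higher and 2 lower, adjusted p = 0.0852). Of the G2/M and mitosis genes, 7 of 38 were lower and 1 was higher (median -0.108, adjusted p = 0.000817, and 0.307 with an estimated correlation). Lists called only with the preset correlation also included fibroblast markers (1 of 7 higher, 3 lower), epithelial identity (3 of 9 lower, median -0.424), extracellular matrix (4 of 39 higher, 12 lower), apoptosis regulators (5 of 29 higher, 2 lower), nucleic acid sensing (2 of 22 higher) and cytosolic ribosomal proteins (median 0.157). Their adjusted p values with an estimated correlation were 0.0706, 0.0906, 0.305, 0.0611, 0.307 and 0.706. With the preset, leaving out untreated replicate 2 ended the calls for epithelial identity (0.0679), matrix (0.0679) and ribosomal proteins (0.73), and treated replicate 1 did so too (0.0603, 0.0691 and 0.0846). Without treated replicate 2 the matrix (0.0526) and fibroblast (0.125) calls were lost, and without treated replicate 3 that for nucleic acid sensing (0.0579). Unfolded protein response and ATF4 targets were not called (2 of 28 higher, 3 lower, median -0.0469, adjusted p = 0.476). Mki67, a proliferation marker, had -0.28 ± 0.21 (adjusted p = 0.485), with 1450 CPM in the untreated replicate 2 that stood apart and 811 and 846 CPM in the other untreated libraries; without that replicate the value was 0.048. The number of genes past the threshold fell to 1032 (528 higher, 504 lower) without replicate 3 of the untreated and 883 (472 and 411) without replicate 2 of the treated wild-type cells, and was 648 (334 and 314) with only these 6 libraries in the fit. It was 2717 (1349 and 1368) without the libraries that stood farthest from their groups (replicate 2 of the untreated wild-type and replicate 1 of the untreated knockout cells, left out together after seeing the data).

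The second comparison asked how knockout cells responded to IFN. Cd274 rose from 2.75 ± 0.377 to 39.9 ± 1.83 CPM (n = 3), a log2 fold change of 3.86 ± 0.12 (SE, adjusted p = 4.06e-10). Serpina3f was at least 1340-fold and Cxcl9 at least 1120-fold higher than in untreated knockout cells, where both had 0 counts. Next came Iigp1 (7.02 ± 0.18, adjusted p = 7.21e-11), Gbp2 (6.78 ± 0.13, adjusted p = 5.22e-12), Gbp4 (6.05), Tgtp1 (6.03), Apol6 (5.89) and Tgtp2 (5.62), most of them interferon-inducible GTPase genes. Tgtp1 and Tgtp2, like the Gbp and Serpina3 genes, are close relatives whose reads could have been split between copies. The largest decreases were in Fam129a (-2.37), the cholesterol exporter gene Abca1 (-2.26 ± 0.16, adjusted p = 8.98e-07), Akap12 (-2.04), Tmem266 (-2.03), the linker histone gene Hist1h1c (-2.02), Htra3 (-1.97), Aqp5 (-1.88) and Tecta (-1.84). The difference between genotypes is tested under the interaction.

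IFN changed 2127 genes in knockout cells, 913 higher and 1214 lower, of which 301 and 346 changed at least 2-fold. The interferon gamma response list rose (36 of 39 members over all genes and adjusted over the list alone, median 3.89, adjusted p = 5.44e-05 with an estimated correlation). So did type I interferon-stimulated genes (17 of 38, or 18 adjusted over the list alone, median 0.447, adjusted p = 0.0417 with an estimated correlation), such as Zbp1 (4.10) and Stat2 (1.46). MHC class I presentation rose (18 of 23, or 19 adjusted over the list alone, median 1.14, adjusted p = 0.0197 with an estimated correlation), with Nlrc5 at 2.1, Tap1 at 2.63 and the class I heavy chain gene H2-K1 at 0.76. Interferon signalling parts were also higher (10 of 22, median 0.449), and so were apoptosis regulators (9 of 29, median 0.290); both had an adjusted p of 0.0139 with an estimated correlation. Chemokines and cytokines (11 of 20 higher, median 1.44), TNF and NF-kB targets (12 of 21, median 0.530), MYC targets (6 of 34, median 0.222) and cholesterol biosynthesis (18 of 24, median 0.740, Insig1 at 1.32) rose with adjusted p values of 0.0139, 0.0139, 0.0417 and 0.00166 with an estimated correlation. Adjusted over the list alone, these lists had 15, 16, 11 and 18 higher members.

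Unfolded protein response and ATF4 target genes fell with IFN in knockout cells (17 of 28, or 19 adjusted over the list alone, median -0.454, adjusted p = 0.0139 with an estimated correlation). Among them were the folate enzyme gene Aldh1l2 (-1.39), the cystine transporter gene Slc7a11 (-1.17) and Nupr1 (-0.75). Replication-dependent histone genes fell too (4 of 17 over all genes and adjusted over the list alone, median -0.699, adjusted p = 0.0355 with an estimated correlation); poly-A selection captures few of their transcripts. Calls for glycolysis and hypoxia (8 of 31 lower), immediate early genes (14 of 27 higher, 4 lower), extracellular matrix genes (7 of 39 higher, 13 lower) and nucleic acid sensing (9 of 22 higher) were lost with an estimated correlation, at adjusted p = 0.232, 0.171, 0.171 and 0.0736. An oxidative phosphorylation call (1 of 30 higher, 1 lower) was lost too (0.716), and with the preset also without untreated knockout replicate 1 (0.367) or treated knockout replicate 3 (0.0796). The number of genes past the threshold was 1361 (620 higher, 741 lower), 1352 (619 and 733) and 1349 (593 and 756) without replicates 1, 2 and 3 of the treated knockout cells, respectively.

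The third comparison asked what the knockout changed without IFN. Cd274 was at 2.75 ± 0.377 CPM in untreated knockout cells against 17.9 ± 1.64 CPM in untreated wild-type cells, a log2 fold change of -2.70 ± 0.12 (SE, n = 3, adjusted p = 8.47e-09). Of the genes that decreased, Cxcl9 had 0 counts in the knockout libraries, at least 149-fold lower. Ms4a4d had 1963 counts in wild-type and 2 in knockout libraries (ratio 1230, 95% counting interval 341 to 10200), and the LIM domain gene Fhl1 had 892 and 3 (ratio 374, interval 128 to 1820). Ifi213 (-9.11), Ifi206 (-7.11), Ifit3b (-6.24 ± 0.14, adjusted p = 5.27e-11), Cxcl11 (-6.17) and Mx1 (-5.63 ± 0.13, adjusted p = 5.27e-11) were also lower; Ifit3b shares sequence with Ifit3, and 41.7% of the exonic bases of Cxcl11 overlapped a gene on the opposite strand. One of 2 entries named Rnf26 was lower as well (876 against 1 count), but it overlaps the other entry and its call (adjusted p = 0.0204) was lost without any one of the 3 knockout libraries (adjusted p 0.0686 to 0.0914). The largest increases were in the extracellular matrix gene Thbs1 (3.32 ± 0.12, adjusted p = 1.55e-09), Sspo (3.16), Ifi27 (2.25), Ppp1r14c (1.94), Sdpr (1.82), the semaphorin gene Sema3c (1.65), Mapt (1.49) and Cyb5a (1.44). For Mapt the call (adjusted p = 0.0213) was lost (adjusted p 0.0571 to 0.0962) without replicate 1 or 3 of either untreated group.

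The knockout changed 2835 genes without IFN, 1073 higher and 1762 lower, and of those that changed at least 2-fold 101 were higher and 811 lower. All 38 tested type I interferon-stimulated genes were lower, over all genes and adjusted over the list alone (median -3.07, camera adjusted p = 2.09e-57, and 0.000872 with an estimated correlation). They included the signal transducer gene Stat2 (-2.27), the sensor gene Zbp1 (-4.55) and Usp18 (-3.64). Of the interferon gamma response list 31 of 39 members were lower (34 adjusted over the list alone, median -2.45, adjusted p = 0.000683 with an estimated correlation), with Cxcl10 at -5.20 and Irf1 at -0.82. MHC class I presentation fell (21 of 23, or 22 adjusted over the list alone, median -0.989, adjusted p = 0.0195 with an estimated correlation), with Tap1 at -1.63, H2-K1 at -1.14 and Nlrc5 at -1.28. Nucleic acid sensing genes fell (15 of 22 lower and 1 higher, or 17 and 1 adjusted over the list alone, median -1.89, adjusted p = 0.0191 with an estimated correlation), among them Ifih1 (-2.46) and Tlr3 (-2.78). Interferon signalling parts (10 of 22, or 12 adjusted over the list alone, median -0.407) and chemokines and cytokines (10 of 20 lower and 1 higher, or 13 and 1 adjusted over the list alone, median -1.15) fell with adjusted p = 0.0191 and 0.0431 with an estimated correlation. Of the receptor genes, Ifnar1 had -0.44 ± 0.10 (adjusted p = 0.00741) and Ifnar2 -0.81 ± 0.10 (adjusted p = 0.000110), and Ifngr1 did not pass the test (0.01 ± 0.09, adjusted p = 0.957). Checkpoint ligand genes, Cd274 included, were lower for 6 of 12 (median -0.646), a list call that was lost with an estimated correlation (adjusted p = 0.0612).

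Unfolded protein response and ATF4 targets were lower in untreated knockout cells (22 of 28, or 23 adjusted over the list alone, median -0.643, adjusted p = 0.00752 with an estimated correlation), with Aldh1l2 at -1.04 and Slc7a11 at -1.31. Cholesterol biosynthesis genes were higher (19 of 24, or 21 adjusted over the list alone, median 0.523, adjusted p = 0.00554 with an estimated correlation), with Acat2 at 0.68 and Insig1 at 0.52. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 147 to 64.5 CPM (-1.19 ± 0.10, adjusted p = 2.8e-06). The p53 target list it belongs to had 9 of 25 members lower and 1 higher (median -0.166, adjusted p = 0.0868 with an estimated correlation). For proliferation genes, 7 of 38 G2/M members were lower (median -0.140, adjusted p = 0.0138), a call lost with an estimated correlation (adjusted p = 0.533) and also without replicate 2 of the wild-type (0.112) or replicate 1 of the knockout cells (0.117). S phase and DNA replication genes were not called (4 of 42 higher, 2 lower, median 0.0703, adjusted p = 0.269), and Mki67 had -0.13 ± 0.21 (adjusted p = 0.722). The sign for Mki67 turned without wild-type replicate 2 (0.20) or knockout replicate 1 (0.048), and without both, a setting chosen after seeing the data, it was 0.37 and passed the test (adjusted p = 0.0162). The cyclin genes Ccnd2 and Ccne1 were at -1.13 ± 0.06 (adjusted p = 7.46e-08) and -0.46 ± 0.07 (adjusted p = 0.000586), whereas the cyclin-dependent kinase gene Cdk4 did not pass the test (0.08 ± 0.07, adjusted p = 0.475).

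Lists for glycolysis and hypoxia (12 of 31 lower), heat shock (6 of 14 lower), apoptosis regulators (8 of 29 lower, 1 higher), and cell cycle inhibitors with D cyclins (4 of 17 lower) were called in untreated knockout cells only with the preset correlation, at adjusted p = 0.0955, 0.0612, 0.0612 and 0.210 with an estimated correlation. With the preset, the call for cell cycle inhibitors with D cyclins also ended without wild-type replicate 2 (0.0994) or knockout replicate 1 (0.117), with the replicate block (0.0527) and without the filter on low counts (0.130). Cytosolic ribosomal protein and oxidative phosphorylation lists (medians 0.193 and 0.205) lost their calls with an estimated correlation (adjusted p = 0.638 and 0.565) and without wild-type replicate 2, the library with the most mitochondrial counts (adjusted p = 0.636 and 0.233). Fibroblast marker genes, which these carcinoma cells also expressed, were lower (5 of 7 over all genes and adjusted over the list alone, median -0.426, adjusted p = 0.0191 with an estimated correlation), including Col1a1 (-2.47) and Dcn (-1.55). BAF subunit genes as a list were not called (5 of 26 higher, 3 lower, adjusted p = 0.352, median 0.102 and mean -0.304). Bcl11a, a member of that list, had 189 counts in untreated wild-type libraries and 0 in knockout libraries, at least 79.3-fold lower. Other lists without a call in this comparison were polycomb and chromatin genes (1 of 25 higher, 2 lower, adjusted p = 0.703), WNT targets (2 of 9 lower, 0.405), TGF-beta targets (4 of 20 higher, 5 lower, 0.523), MHC class II genes (1 of 6 lower, 0.163), markers of macrophages (1 of 6 lower, 0.460) and markers of endothelium (1 of 5 lower, 0.759). The number of genes past the threshold was 1494 (380 higher, 1114 lower) with only these 6 libraries in the fit and 2026 (635 and 1391) without knockout replicate 1, and limma on deposited TPM of at least 1 on average split its calls into 1076 higher and 1154 lower.

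**Figure D2:**
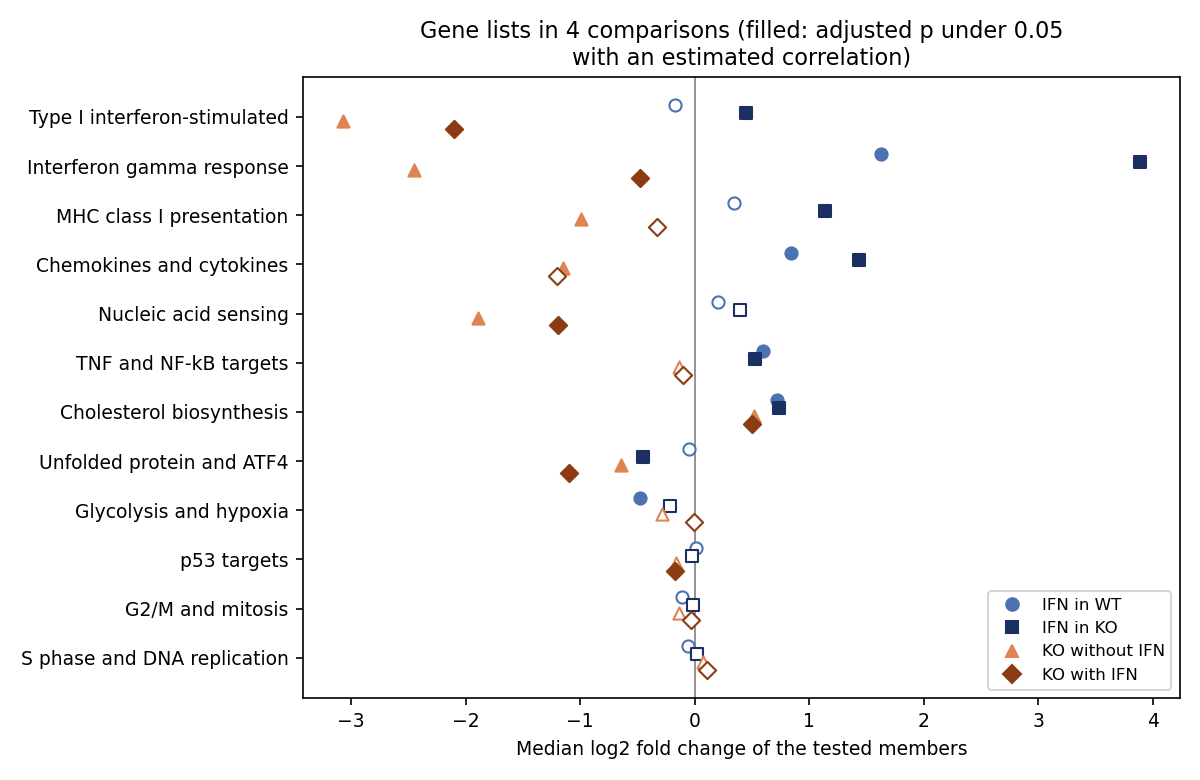
Median log2 fold change of the tested members of 12 gene lists in the 4 comparisons of groups, with filled symbols where the adjusted p with an estimated correlation was under 0.05. The interferon lists lay furthest from 0, at -3.07 for type I genes in untreated knockout cells and 3.89 for interferon gamma response genes after IFN in knockout cells.

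The fourth comparison asked what the knockout changed in the presence of IFN. Cd274 was lower in knockout cells here too, at 39.9 ± 1.83 against 112 ± 9.26 CPM (log2 fold change -1.49 ± 0.11, SE, n = 3, adjusted p = 1.33e-06). Fhl1 had 470 counts in wild-type libraries and 0 in knockout libraries, at least 194-fold lower. Other large decreases were in Ifi213 (-8.42), Ms4a4d (-6.75), Rsad2 (-4.90), Mx1 (-4.86 ± 0.13, adjusted p = 4.94e-10), Ifit3b (-4.82), Lingo1 (-4.72) and the cytokine receptor gene Il2rg (-4.71), of which 30.5% of exonic bases overlap another gene on the same strand. Increases were largest for Sspo (3.40 ± 0.28, adjusted p = 4.1e-06), the activin antagonist gene Fst (1.96), Cdh26 (1.87), Ppp1r14c (1.84), Sema3a (1.83), Thbs1 (1.82), Gas7 (1.58) and Tmem184a (1.47). Gas7 (adjusted p = 0.0161) lost its call without replicate 1 of the treated wild-type cells (adjusted p = 0.0581) and without replicate 1 (0.0564) or 3 (0.0540) of the treated knockout cells. Irf1 (0.20 ± 0.07, adjusted p = 0.0828) did not pass the test with IFN.

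With IFN the knockout changed 2622 genes, 852 higher and 1770 lower, and 84 and 885 by at least 2-fold. All 38 tested type I interferon-stimulated genes were again lower, over all genes and adjusted over the list alone (median -2.10, adjusted p = 0.00185 with an estimated correlation), with Usp18 at -3.52 and Ifit1 at -4.30. Of the interferon gamma response list 19 of 39 members were lower and 2 higher (21 and 4 adjusted over the list alone, median -0.473, adjusted p = 0.0273 with an estimated correlation); Cxcl10 was at -2.33 and Cxcl9 at -1.97. Nucleic acid sensing genes were lower (12 of 22, or 13 adjusted over the list alone, median -1.19, adjusted p = 0.0449 with an estimated correlation). Unfolded protein response and ATF4 targets fell (25 of 28, or 26 adjusted over the list alone, median -1.10, adjusted p = 0.00185 with an estimated correlation), with Slc7a11 at -2.30, Atf3 at -1.89, Aldh1l2 at -1.88 and Herpud1 at -1.39. Cholesterol biosynthesis rose (17 of 24, or 21 adjusted over the list alone, median 0.499, adjusted p = 0.00242 with an estimated correlation), with Cyp51 at 0.92 and Insig1 at 0.85. The p53 targets fell (8 of 25 lower and 1 higher, or 10 and 2 adjusted over the list alone, median -0.173, adjusted p = 0.0449 with an estimated correlation), with Gadd45a at -1.58, Sesn2 at -1.32 and Cdkn1a at -1.14. Fibroblast markers fell (4 of 7 lower, or 4 lower and 1 higher adjusted over the list alone, median -0.772, adjusted p = 0.0449 with an estimated correlation).

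S phase and DNA replication genes were higher in treated knockout cells than in treated wild-type cells for 12 of 42 members, with 1 lower, over all genes and adjusted over the list alone. The list's median was 0.111, and its call (adjusted p = 0.00207) was lost with an estimated correlation (adjusted p = 0.0759). Among these genes were Prim1 (0.60), Rfc5 (0.53), Pole (0.47) and Mcm6 (0.35). Mki67 did not pass the test (0.38 ± 0.21, adjusted p = 0.280), though it passed with only these 6 libraries in the fit (0.37, adjusted p = 0.0130) and without the untreated libraries that stood apart (0.38, adjusted p = 0.00333). The G2/M list did not pass either (2 of 38 higher, 5 lower, adjusted p = 0.528). Calls for MHC class I presentation (9 of 23 lower), checkpoint ligands (6 of 12 lower), chemokines and cytokines (10 of 20 lower, 1 higher), YAP targets (10 of 25 lower), heat shock (3 of 14 lower), interferon signalling parts (7 of 22 lower, 2 higher) and histones (3 of 17 lower) were also lost with an estimated correlation. Their adjusted p values were then 0.202, 0.109, 0.0797, 0.0797, 0.0797, 0.179 and 0.127. The same held for MHC class II genes (2 of 6 lower, 0.266), whose call also ended without treated wild-type replicate 3 (0.0570) or treated knockout replicate 2 (0.0553), and for mitochondrially encoded genes (1 of 13 higher, median 0.589, 0.604). Mitochondrial genes held 2.62% to 2.99% of counts in treated knockout and 1.52% to 2.63% in treated wild-type libraries. The number of genes past the threshold was 1726 (462 higher, 1264 lower), 1771 (487 and 1284) and 1811 (495 and 1316) without replicates 1, 2 and 3 of the treated knockout cells and 1847 (498 and 1349) without replicate 2 of the treated wild-type cells. It was 3561 (1437 and 2124) with only these 6 libraries in the fit, 4457 (1922 and 2535) without the untreated libraries that stood apart, and 1875 (722 and 1153) by limma on deposited TPM of at least 1 on average.

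Genes on chromosomes 9 and 16 were lower in knockout cells as a body, over genes with a mean of at least 2 CPM. Without IFN the median log2 fold change was -0.265 over 659 genes of chromosome 9 and -0.290 over 350 genes of chromosome 16, against -0.0469 to 0.0943 for the other chromosomes. With IFN the medians were -0.234 and -0.249, against -0.0679 to 0.147 elsewhere. Of all genes tested, 8.29% lay on these chromosomes, and they held 360 of the 1762 genes called lower without IFN (20.4%) and 317 of the 1770 with IFN (17.9%). Ifnar1, Ifnar2, Ifngr2 and Mx1 lie on chromosome 16. The IFN comparisons had medians of -0.0135 and 0.00538 on chromosome 9.

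**Figure D3:**
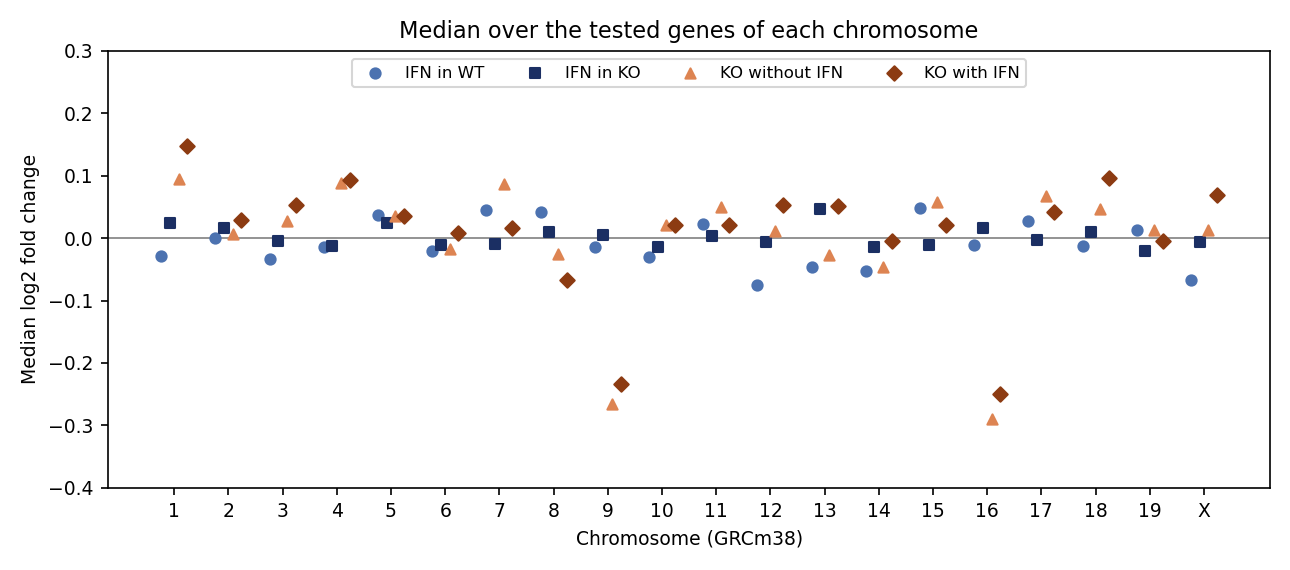
Median log2 fold change of tested genes with a mean of at least 2 CPM on each chromosome (GRCm38) in the 4 comparisons of groups. Chromosomes 9 and 16 lay between -0.29 and -0.234 in both knockout comparisons, and near 0 in both IFN comparisons.

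The last comparison tested whether the IFN response differed between genotypes. The difference in log2 fold change with IFN, knockout minus wild type, was above 0 for 118 genes and below 0 for 52, 170 in total, of which 85 and 26 differed at least 2-fold. The largest positive differences were in Iigp1 (5.0 ± 0.21, adjusted p = 4.24e-08), Tgtp1 (3.92), Gbp2 (3.91 ± 0.15, adjusted p = 1.58e-08), Tgtp2 (3.69), Cxcl11 (3.54), Olfr56 (3.51) and the lipocalin gene Apod (3.44). For Gbp2, levels went from 6.45 to 708 CPM in knockout and from 79.3 to 577 CPM in wild-type cells. Cxcl10 had 2.87, Tap1 1.44, Irf1 1.02 and Nlrc5 0.85. Cd274 had 1.22 ± 0.16 (adjusted p = 0.00127), and its level with IFN stayed lower than in wild-type cells; limma on log2(TPM + 1) gave an adjusted p of 0.0595. For Cxcl9, with 0 counts in untreated knockout cells, the fitted difference depends on the prior count and is no measure of fold, and limma on log2(TPM + 1) put it at -0.02. Differences were below 0 for Ifi27 (-2.22 ± 0.24, adjusted p = 0.000224), Abca1 (-2.03), Mcf2l (-1.63), Ublcp1 (-1.56), Ctgf (-1.52), Tenm4 (-1.52), Thbs1 (-1.50) and Krt16 (-1.44). For Mcf2l and Krt16 (adjusted p = 0.0318 and 0.0254) the call was lost without any of 9 and any of 7 libraries, respectively.

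The interferon gamma response list had larger log2 fold changes in knockout cells (25 of 39 members above 0, or 28 above and 2 below adjusted over the list alone, median 1.59, adjusted p = 0.000159 with an estimated correlation). Type I genes had differences above 0 as well (12 of 38, or 22 adjusted over the list alone, median 0.575, adjusted p = 0.0163 with an estimated correlation). Unfolded protein response and ATF4 targets fell with IFN in knockout cells (median -0.454) and were not called in wild-type cells (median -0.0469), with differences below 0 for 6 of 28 members (21 adjusted over the list alone, median -0.410, adjusted p = 0.0139 with an estimated correlation), with Herpud1 at -0.76 and Chac1 at -1.43. For MHC class I presentation (9 of 23 above 0, or 16 above and 1 below adjusted over the list alone, median 0.715) the call was lost with an estimated correlation (adjusted p = 0.0571). DESeq2 called 357 genes for the interaction (215 above 0, 142 below) and limma on log2(TPM + 1) called 111 (81 and 30), and 265 (186 and 79) were called without both libraries that stood apart. The 52 genes below 0 became 34 and 29 without treated wild-type replicates 1 and 2, and 29, 32 and 32 without treated knockout replicates 1, 2 and 3.

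**Figure D4:**
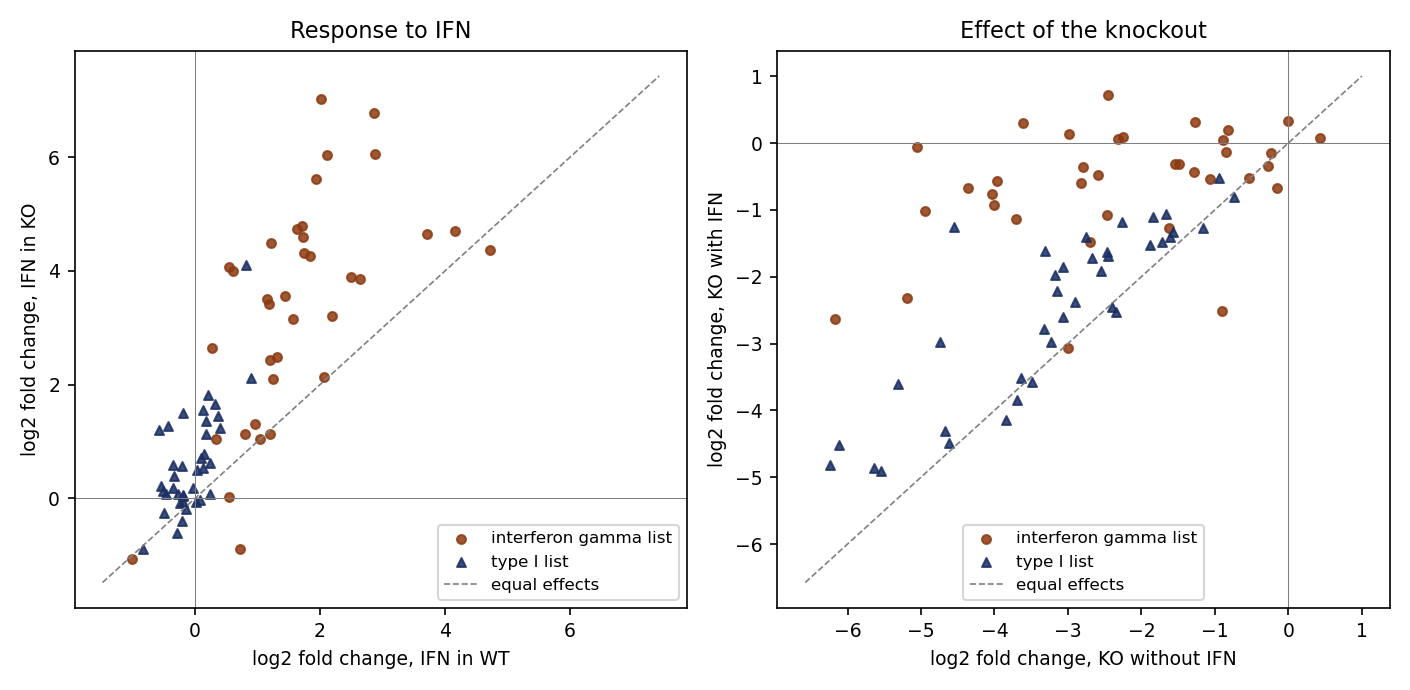
Log2 fold changes of the interferon gamma response list (39 genes) and the type I interferon-stimulated list (38 genes), for the response to IFN in wild-type against knockout cells and for the knockout effect without against with IFN, a point per drawn gene and a dashed line of equal effects. Cxcl9, Serpina3f and Ido1 of the interferon gamma list, with 0 counts in untreated knockout cells, are not drawn. Medians of the interferon gamma list, over all 39 genes, were 1.63 in wild-type and 3.89 in knockout cells, and medians of the type I list were -3.07 without and -2.10 with IFN.

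Calls were also compared between conditions, using pairs of comparisons that share no library. The knockout raised 413 genes and lowered 1109 both without and with IFN, against 54.82 and 187 for independent lists of these sizes, and 15 genes were called in opposite directions. Across genes, which are not independent replicates, the fold changes correlated at a Pearson r of 0.70 and a Spearman correlation of 0.516. IFN raised 452 genes and lowered 445 in both genotypes, against 42.54 and 57.29 for independent lists, and 10 genes went in opposite directions. The IFN fold changes of both genotypes correlated at 0.475 (Pearson) and 0.402 (Spearman) across genes. Over genes called in wild-type cells the slope of the knockout on the wild-type response was 1.02, and over those raised in wild-type cells it was 1.37. Both slopes include genes with 0 counts in untreated knockout cells, such as Cxcl9 and Serpina3f, whose fitted values depend on the prior count. The shared count for IFN was 596 without replicate 2 of the treated wild-type cells and 1551 without both libraries that stood apart.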

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

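The tests of explanations in this part were chosen after the result was seen, as were the reading of draws by the labels they kept and the interaction counts under redrawn genotype labels; the redrawn treatment labels were planned. A difference between groups brought 170 genes here: by the interaction term, their IFN effect differed between knockout and wild-type cells. Differences in log2 effect were 5.0 for Iigp1, 3.92 for Tgtp1, 3.91 for Gbp2, 3.69 for Tgtp2, 3.54 for Cxcl11, 3.51 for Olfr56, 3.44 for Apod, 2.87 for Cxcl10, 1.44 for Tap1, 1.22 for Cd274, 1.02 for Irf1 and 0.85 for Nlrc5. The difference was below 0 for Ifi27 (-2.22), Abca1 (-2.03), Mcf2l (-1.63), Ublcp1 (-1.56), Ctgf (-1.52), Tenm4 (-1.52), Thbs1 (-1.50) and Krt16 (-1.44). For Cxcl9 the fitted value of 8.04 is set against 0 counts in untreated knockout cells, depends on the prior count and is not comparable with the others. The annotated span of Olfr56 holds other interferon-inducible genes.

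Of the 34 lists tested, 19 differed between genotypes by camera with the preset correlation. Median differences were 1.59 for the interferon gamma response, 0.575 for type I interferon-stimulated genes and -0.410 for unfolded protein response and ATF4 targets, the 3 lists whose call also held with an estimated correlation. The others, with that adjusted p between 0.0571 and 0.664, were interferon signalling parts (0.125), MHC class I presentation (0.715), checkpoint ligands (0.184), chemokines and cytokines (0.378), S phase (0.0626), cell cycle inhibitors and D cyclins (0.333), MYC targets (-0.106), cytosolic ribosomal proteins (-0.234), glycolysis and hypoxia (0.249), oxidative phosphorylation (-0.210), YAP targets (-0.161), apoptosis regulators (0.274), nucleic acid sensing (0.244), replication-dependent histones (-0.526), mitochondrially encoded genes (0.965) and markers of endothelium (-1.12). Signs are those of knockout minus wild type: glycolysis and hypoxia genes, for example, fell less in knockout cells (-0.216 against -0.475). Leaving out untreated wild-type replicate 2 ended the call for mitochondrially encoded genes (adjusted p = 0.277), cytosolic ribosomal proteins (0.595) and oxidative phosphorylation (0.453, and 0.0713 without untreated knockout replicate 1). The call for S phase was lost without untreated wild-type replicate 1 (0.0895) or 3 (0.0619), and that for apoptosis regulators without untreated knockout replicate 3 (0.0517). For MYC targets it was lost without untreated wild-type replicate 2, treated wild-type replicate 1 or 2, untreated knockout replicate 2 or 3, or treated knockout replicate 1 (0.0702 to 0.175). For endothelium it was lost without untreated wild-type replicate 2 or 3, treated wild-type replicate 3, untreated knockout replicate 1 or 3, or treated knockout replicate 1 (0.0685 to 0.191).

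The larger IFN response of knockout cells, larger as a log2 fold change, was weighed. In CPM the order varied: with IFN, Cd274 rose by fewer CPM in knockout than in wild-type cells, and Gbp2 by more. Low counts in untreated knockout libraries as the whole cause are argued against: the 27 members of the interferon gamma list with at least 2 CPM in those libraries had a median difference of 2.23, and 18 of them passed the test. A lower starting level with an equal end level did not hold for most of these genes: of 106 with a difference above 0 that rose in knockout cells, 76 still differed from wild type with IFN, 9 higher and 67 lower. Without IFN 103 were lower in knockout cells, which selection by the interaction favours. Over all 106 the median knockout effect was -2.79 without and -0.923 with IFN. Most thus started lower and came closer to wild type, so a lower starting level as the source of the larger response is not argued against. The knockout itself and any difference between clones or cultures stay open, as untested.

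Redrawn treatment labels within each genotype (100 draws, the real one included) gave as many genes for the interaction (170) in 3 draws, with 595 and 198 genes in the highest others. The draws with 595 and 198 genes exchanged and kept, respectively, every label of the knockout cells and mixed those of the wild-type cells. The IFN effect of knockout cells therefore enters these counts. A draw that mixes the labels of knockout cells moves their IFN effect into the spread between replicates, so it calls few genes whether or not the genotypes differ; the 92 such draws called at most 3. The 7 other draws that kept or exchanged every label of the knockout cells called 62 genes or more, 2 of them as many as the real labels, and are too few for a share under 0.05. Redrawn genotype labels within each treatment gave 4483 genes where all labels of the treated cells were exchanged, 42 to 88 in 6 draws that kept the untreated labels and mixed the treated ones, and at most 10 in the 92 others, with the same limit. The draws therefore do not decide whether chance can be excluded for the interaction.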

How the results depend on the processing

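Alternatives with both outlying libraries left out (untreated wild-type replicate 2 and untreated knockout replicate 1), with the GC trend removed and without chromosomes 9 and 16 were chosen after seeing the data. Of the counts of genes, 70 stayed within 1.5 times their value and 18 moved further; when libraries were left out in turn, 53 stayed and 7 moved. Named genes kept their direction and side of the threshold in 3365 tests, lost the call in 208, gained it in 2 and reversed in 4; leaving out libraries gave 3004, 411, 0 and 5. For list tests the numbers were 436 kept, 76 lost and 4 reversed, and 592, 37 and 1. DESeq2 size factors and the fit without a filter moved the median of all genes by less than 0.1.

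A required 2-fold change left 352 genes for IFN in wild-type cells, 647 for IFN in knockout cells, 912 for the knockout without IFN, 969 with IFN and 111 for the interaction, with 598 shared between the knockout effects and 221 between the IFN effects, which follows from the stricter rule. With only the libraries compared, IFN in wild-type cells called 648 and the knockout without IFN 1494, while IFN in knockout cells called 2680 and the knockout with IFN 3561; the cause was not tested. Groups from the characteristics exchange these contrasts (2835 and 1564). Without both outlying libraries the counts were 2717 for IFN in wild-type cells, 4457 for the knockout with IFN and 265 for the interaction, with 1551 shared between the IFN effects. Both libraries are untreated, so the change from 2622 to 4457 for the knockout with IFN came through what all groups share in the fit. That covers the spread, the filter and the scaling, which were not told apart. For the interaction, DESeq2 called 357, limma on log2(TPM + 1) 111, and limma with a mean TPM of at least 1 113; the cause was not tested.

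Leaving out 1 library at a time gave 883 (without treated wild-type replicate 2) to 1783 (without untreated wild-type replicate 2) genes for IFN in wild-type cells and 1349 to 1756 for IFN in knockout cells. The knockout called 2026 to 2656 without IFN and 1726 to 2246 with IFN, and the interaction 118 to 212. Shared genes numbered 1151 to 1747 for the knockout and 596 to 1197 for IFN. Removing the GC trend gave 1866, 2560, 3096, 3184 and 222 genes in the order above, and leaving out chromosomes 9 and 16 gave 1449, 1983, 2398, 2259 and 169. The replicate numbers do not pair the libraries (deviations of equal numbers correlated at -0.162 to 0.113); with them as a block the counts were 1282, 1869, 2522, 2333 and 143, with 1345 and 756 shared.

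Among named genes, the reversals other than that of Cxcl9 concerned values that had not passed the test. Mki67 after IFN in wild-type cells ranged from -0.42 to 0.048 without 1 untreated wild-type library and was 0.048 without both outlying libraries. For the knockout without IFN it went from -0.28 to 0.20 (without wild-type replicate 2), and was 0.05 without knockout replicate 1 and 0.37 without both (adjusted p = 0.0162). The interaction of Cxcl9 was -0.020 by limma on log2(TPM + 1). The interaction of Smarcd1 ranged from -0.090 to 0.18 and was -0.12 without both. Cytosolic ribosomal proteins, called after IFN in wild-type cells, had adjusted p values from 8.88e-06 to 0.73 (without wild-type replicate 2), and 0.706 with an estimated correlation. Without both libraries that list reversed with 0.936 there, 0.431 for the knockout without IFN and 0.697 for the interaction, and oxidative phosphorylation with 0.769 for the interaction; the cause was not tested. At these depths a count of 0 in a group allows bounds such as the 79.3-fold given for Bcl11a.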

Other observations

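Tests of explanations for the interferon-stimulated genes and for chromosomes 9 and 16 were chosen only after the result was seen, and the splits and redrawn labels were planned. Ifnb1 (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), which encodes interferon beta, had 79, 44 and 56 counts in the untreated wild-type libraries and 0, 0 and 1 in the untreated knockout libraries (ratio 225, 95% counting interval 39.9 to 8940). With IFN it had 66, 67 and 56 counts in wild-type and 1, 0 and 0 in knockout libraries (ratio 234, interval 41.5 to 9290). Of other named cytokine and inflammasome genes, those lower in untreated knockout cells included Il6 with 94 against 2 counts (ratio 59.1, interval 15.9 to 495), Casp1 with 70 against 2 (ratio 44, interval 11.7 to 371) and Ccl5 (-3.87 ± 0.25, adjusted p = 2.44e-07). TNF and NF-kB targets as a list were not called in this comparison (4 of 21 higher, 5 lower, adjusted p = 0.323).

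Matrix genes moved in both directions. With IFN, 4 of 39 members of the extracellular matrix list were higher and 12 lower in wild-type cells, and 7 higher and 13 lower in knockout cells (adjusted p = 0.305 and 0.171 with an estimated correlation). Fibroblast markers had 3 of 7 lower and 1 higher in each genotype (adjusted p = 0.0104 and 0.0951, and 0.0706 and 0.190 with an estimated correlation). Of the matrix list, Col1a2 had -1.59 in wild-type and -1.59 in knockout cells, and Col3a1 -1.32 and -1.31. The knockout lowered Col1a1 (-2.47 without and -2.68 with IFN), the osteopontin gene Spp1 (-1.37 and -1.80) and the lysyl oxidase-like gene Loxl2 (-1.46 and -1.02), while Thbs1 rose. The matrix list as a whole was not called for the knockout (adjusted p = 0.177 without and 0.126 with IFN).

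The lower interferon-stimulated genes in untreated knockout cells were weighed first. The outlying libraries (untreated wild-type replicate 2 and untreated knockout replicate 1) are argued against, since without both the type I list median was -2.87, against -3.07 with them (members from -6.33 to -0.875). Smarcd1 was not lower in the libraries that the characteristics call untreated knockout (0.183, SE 0.128), but editing need not lower the transcript, so this alone does not decide. The interferon gamma list argues against exchanged labels. With groups from the characteristics, its mean log2 CPM would fall with IFN from 4.503 to 2.17 in wild-type and from 6.453 to 5.845 in knockout cells. Less interferon made by the cells themselves is a candidate explanation. With added IFN, type I genes stayed further below wild type than interferon gamma genes, by a difference in medians of -1.62. The 95% interval over genes was -2.43 to -1.10, from 10000 resamples that treated genes as independent. Medians without IFN already differed (-3.07 and -2.45). IFN also raised the interferon gamma list in wild-type cells (median 1.63), where the type I list was not called. The difference therefore does not single out this explanation. Reading it so also assumes an added interferon of the gamma type, which the labels do not state, and a difference between clones or cultures was not tested.

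Lower expression over chromosomes 9 and 16 in knockout cells was weighed second, with a median difference of -0.299 from other genes without IFN. GC content is argued against (-0.282 after removal of each library's trend), and so are the outlying libraries (-0.291 without both) and a few strongly lowered genes, since 21 of 21 windows of up to 50 genes lay below 0 (-0.525 to -0.125). One of these held 9 genes and the others 50. Elsewhere there were 229 windows, 17 of them with fewer than 50 genes, and 12 of the 229 lay as low. Fewer copies of both chromosomes in some or all knockout cells may account for it. The difference was -0.277 in the treated libraries, which share no library with the untreated ones, and -0.00118 and 0.00552 in the IFN contrasts. Any lasting difference between knockout and wild-type cells over these chromosomes would give such values, so they do not single out fewer copies. Without IFN the median gene of chromosomes 9 and 16 was at 83.2% and 81.8% of its wild-type level, over genes of at least 2 CPM. The type I genes outside these chromosomes had a median of -2.98 in untreated knockout cells, so that list moved mostly on other chromosomes. That concerns the positions of its members only, and a link between both patterns was not tested.

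For each comparison of 3 with 3 libraries, 1 of the 10 splits of the 6 samples, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 1564, 2127, 2835 and 2622, and the highest other splits called 1, 1, 1 and 2 genes. For the 897 genes shared between the IFN effects, 1 of 100 draws of the treatment labels, the real one, gave as many (highest other 1), and for the 1522 shared between the knockout effects 1 of 100 draws of the genotype labels did (highest other 15). That share speaks only against labels that carry no effect in either comparison of a pair. These draws break the effects themselves, so low shared counts in them follow from the redrawing. They do not test whether the sharing exceeds that of independent effects.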
